A study of Mus musculus with 9 samples.

How the data were processed

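Striatal RNA from 9 female mice on a mixed C57BL/6 and CBA background was analysed, 5 carrying the R6/2 transgene and 4 wild-type. R6/2 mice carry exon 1 of the human huntingtin gene with an expanded CAG repeat and are used as a model of Huntington disease. The labels give an age of 12 weeks, and in days 85 for the 4 wild-type mice and R62_86, and 83 for the other 4 R6/2 mice. Each mouse was 1 array, and mice are named by genotype and animal number, with R62 for R6/2.

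The deposited values were log2 expression values of 45101 probe sets per array, made with RMA of the affy package per the submitters' processing notes. RMA subtracts background, gives the arrays a shared distribution of intensities and summarises the probes of a probe set on the log2 scale. The biotin label was introduced by in vitro transcription per the labels' protocols, which starts at the 3' end of transcripts, so degraded RNA lowers probe sets far from that end. Because RMA makes the arrays share 1 distribution, a change in the total amount of RNA per cell could not be seen, and each difference is relative to the other genes of the array. Software versions, and which arrays were normalized together, are not given in the sources used here. The lowest correlation of 2 arrays over all probe sets was 0.979 and the highest was 0.995, and at most 3.93% of probe sets had identical values in 2 arrays, so each array was counted as 1 replicate. For arrays, their number limits the precision.

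Probe sets were named through the platform annotation, in which 35890 were listed. Of these, 34945 named exactly 1 gene and 932 named several genes. A further 9211 probe sets were not listed and stay unnamed here, and 64 were manufacturer controls. Through gene identifiers, 34741 of the probe sets naming 1 gene matched the RefSeq gene table of the GRCm38.p6 assembly, which gave positions, and 204 kept the annotation's symbol. For each of 18193 genes, the probe set with the highest mean over all arrays was used, and 9010 genes had more than 1. No filter on dim probe sets was set. Of 142 genes chosen by the rule for named genes, Arpp21 alone had a probe set past the threshold against the direction of the brightest one, and 22 of all genes had probe sets past the threshold in both directions. Some items are not reported here.

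Genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. A log2 difference is R6/2 minus wild-type. A total of 33 gene lists for cell types, pathways and neighbouring tissues held 630 entries, of which 574 were measured. They were fixed with the design, the tests, the rule for named genes and the first set of alternatives before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation and with fry. Besides, the members' mean log2 value per mouse (the list score) was compared between genotypes by an exact two-sided permutation test over the 126 splits of 9 mice into 4 and 5, whose smallest p is 0.00794. Differences between list scores were tested in the same way. Changed genes were counted per chromosome with Fisher's exact test and in windows of 10 Mb.

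The genes named in the text were those of a fixed rule. It took the 10 highest and 10 lowest log2 differences among genes past the threshold whose groups did not overlap, without symbols that are only clone or predicted-gene names. It further took a fixed set of striatal and disease genes (Drd1, Drd2, Penk, Pdyn, Tac1, Ppp1r1b, Pde10a, Cnr1, Bdnf, Gfap and Htt among them), and up to 4 members of each list, namely the 3 with the smallest p and the best-supported member against the sign of the list's median. Neurod1, Neurod6, Slc17a7, Arc and the gene families named by symbol were chosen after their values were seen.

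Alternatives were every probe set tested on its own, the mean of a gene's probe sets, the brighter 50% of genes, quantile normalization, centring on the median or on 5 measured housekeeping genes of 8 fixed ones, eBayes with trend and robust settings, array weights, a test without moderation, 3 stricter thresholds, age as a covariate, and each mouse left out in turn. The cortex list score as a covariate and 2 sets of arrays left out were added after the data were seen. On simulated values for this comparison, with all 18193 genes, limma recovered 77.6% of 67 genes changed by 0.5 on the log2 scale, 100% of 67 changed by 1 and 98.5% of 65 changed by 2, and 4.98% of its calls were false. Camera found the simulated list that had been shifted and 0 of the other lists. The simulated genes were drawn independently, whereas the estimated correlation within the shared spiny neuron list was 0.71. These values therefore do not show how often genes or lists that vary together are called falsely. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.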

Results

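Gene expression was measured on whole-genome arrays in the striatum of 9 female mice at 12 weeks of age. The 5 R6/2 mice (R62_86, R62_95, R62_105, R62_107 and R62_109) carry exon 1 of human mutant huntingtin, and the 4 wild-type mice (46, 47, 49 and 66) were the controls. The comparison asked which striatal transcripts differed between R6/2 and wild-type mice at this age. Values are log2 expression, and the median of the arrays lay between 5.37 and 5.45.

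The lowest differences in R6/2 mice included markers of striatal projection neurons. They belonged to Ryr1, a calcium release channel (log2 difference -3.12 ± 0.28, SE), Egr2, an activity-induced transcription factor (-2.85 ± 0.26), Scn4b, a sodium channel subunit (-2.71 ± 0.25), and Npas4, an activity-induced transcription factor (-2.55 ± 0.26). Scn4b was 12.07 ± 0.28 (SD, n = 4) in wild-type and 9.36 ± 0.55 (SD, n = 5) in R6/2 mice, 0.153 of the wild-type level. Car12, a carbonic anhydrase (-2.50), Abi3bp (-2.43), Gpx6, a glutathione peroxidase (-2.35), Dmkn (-2.31), Phex (-2.18) and Coch (-1.98) completed the 10 lowest. In R6/2 mice Phex lay at 2.91 to 3.17 and Abi3bp reached down to 3.38, near the dim end of the arrays, so their differences may be understated. The rises were smaller. Prdm8, of a family of zinc finger regulators, rose by 1.83 ± 0.40, C1ql3, a secreted synaptic protein, by 1.69 ± 0.37, Sfmbt2, a Polycomb group gene, by 1.54 ± 0.18 and Gng4, a G protein subunit, by 1.46 ± 0.21. Gprasp2, whose product binds G protein-coupled receptors, rose by 1.38 ± 0.08 and had the smallest adjusted p of the 10 (3.19e-05). Ipcef1 (1.36), Fhod3 (1.34), Camk2n2, an inhibitor of calmodulin kinase II (1.30), Glra3, a glycine receptor subunit (1.29), and Col11a1 (1.26) followed. The call of Fhod3 ended without wild-type mouse 66 (adjusted p 0.0546). Without limma's moderation of the variance, Prdm8, C1ql3, Ipcef1, Fhod3, Glra3 and Col11a1 did not pass (adjusted p 0.0515 to 0.0771). The same 6 did not pass with the score of the cortex marker list as a covariate, where Prdm8 was 0.66 ± 0.24, C1ql3 0.55 ± 0.15 and Ipcef1 0.49 ± 0.14. In wild-type mice 46, 47, 49 and 66, C1ql3 was 8.02, 7.72, 6.41 and 6.31, in the order of their cortex scores. Gprasp2 (1.22 ± 0.10), Sfmbt2 (1.78 ± 0.24), Gng4 (0.91 ± 0.18) and Camk2n2 (0.68 ± 0.13) and the 10 lowest genes passed with this covariate.

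**Figure D1:**
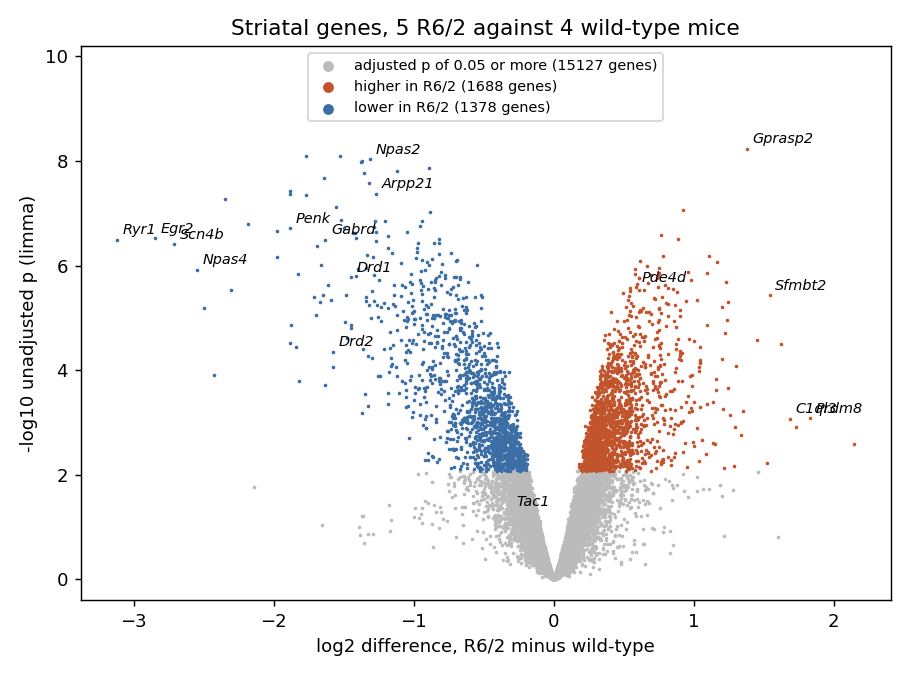
Each point is 1 of 18193 genes, with the log2 difference between R6/2 and wild-type mice on the x axis and -log10 of limma's unadjusted p on the y axis. The 1688 genes higher and 1378 genes lower in R6/2 mice at an adjusted p under 0.05 are coloured, and the differences on the lower side reach further from 0.

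In all, 3066 of 18193 genes (16.9%) passed the threshold, 1688 higher and 1378 lower in R6/2 mice. By at least 1 on the log2 scale, 48 were higher and 150 lower. In 2536 of the changed genes the 2 groups did not overlap, and 17.3% of all genes tested showed no overlap against 1.59% by chance. Centring on the housekeeping genes moved the median of all genes from -0.02 to -0.12 and the share of higher calls from 55.1% to 21.6% (696 higher, 2525 lower), so small rises hold only relative to the other genes of the array. Sdha, among these housekeeping genes, itself gave 0.24 ± 0.09 (SE, adjusted p 0.0903), which adds to that shift. With age as a covariate 30 genes passed, since R62_86 alone shares the wild-type age. An effect of the day of dissection that followed age would be confounded with genotype in the same way. With the cortex list score as a covariate 506 genes passed, and 882 passed without the 3 arrays richest in choroid plexus transcripts (wild-type 47 and 66, R62_107). Without wild-type mouse 47, 1120 genes were higher.

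The shared markers of spiny projection neurons, the main neurons of the striatum, fell throughout. All 30 measured members were lower past the threshold, and 30 adjusted over the list alone, with a median log2 difference of -1.19 (camera adjusted p = 1.29e-26). With an estimated correlation the list gave an adjusted p = 0.314. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, fell by 1.70 ± 0.22 (SE, adjusted p 0.000691). Pde10a, a phosphodiesterase enriched in these neurons, fell by 1.48 ± 0.17, and the cannabinoid receptor gene Cnr1 by 1.33 ± 0.13. Arpp21, a cyclic AMP-regulated phosphoprotein, fell by 1.27 ± 0.09, although 1 of its probe sets rose by 0.66 (adjusted p 0.0446) and the mean of its probe sets did not pass (adjusted p 0.216). The list score was lower in all 5 R6/2 mice, by 1.0 to 1.75, than the wild-type mean (exact permutation p = 0.00794, the smallest possible). The score of cortex projection neuron markers in the same R6/2 mice lay 0.21 to 1.19 above the wild-type mean. With that score as a covariate 21 of the 30 members passed, without the 3 arrays richest in choroid plexus transcripts 24, and with age as a covariate 1, at a median of -1.06.

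**Figure D2:**
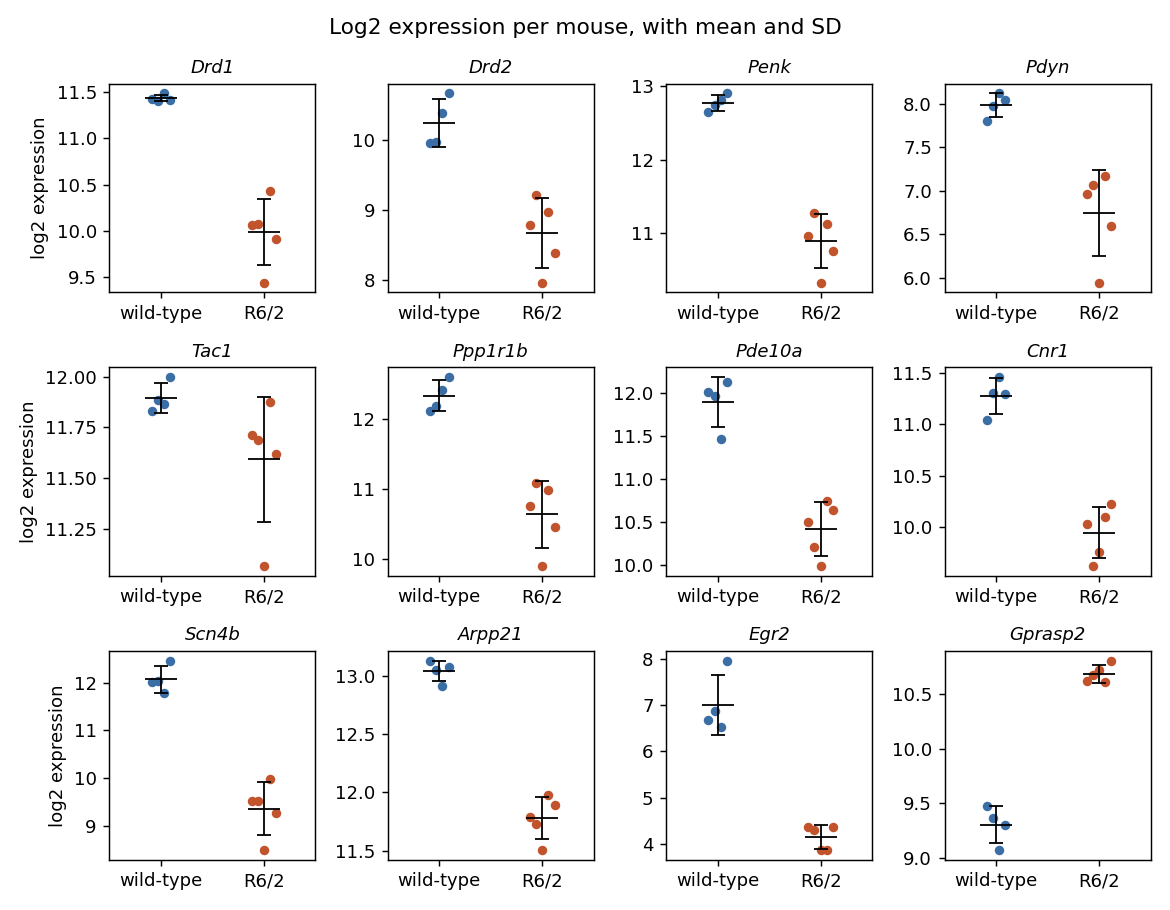
Log2 expression (y axis) of 12 genes in each mouse, 4 wild-type and 5 R6/2, with the mean (horizontal bar) and SD (error bar) of each group. Drd1, Drd2, Penk, Pdyn, Ppp1r1b, Pde10a, Cnr1, Scn4b, Arpp21 and Egr2 show no overlap between groups on the lower side, Gprasp2 none on the higher side, and Tac1 overlaps.

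Markers of both output pathways were lower, and those of the indirect pathway by more. Of 5 indirect pathway markers 4 fell, and 4 adjusted over the list alone (median -1.58, camera adjusted p = 0.00048; adjusted p = 0.314 with an estimated correlation). Penk, the precursor of enkephalin, fell from 12.77 ± 0.11 (SD, n = 4) to 10.89 ± 0.37 (SD, n = 5), to 0.271 of the wild-type level. The orphan receptor gene Gpr6 fell by 1.67 ± 0.17 and the dopamine receptor gene Drd2 by 1.58 ± 0.24. The kainate receptor gene Grik3 gave 0.12 ± 0.17 (adjusted p 0.669). Of 8 direct pathway markers 5 fell, and 5 adjusted over the list alone (median -0.46, camera adjusted p = 0.000839; adjusted p = 0.383 with an estimated correlation). Drd1 fell by 1.45 ± 0.16, the transporter gene Slc35d3 by 1.30 ± 0.21 and Pdyn, the dynorphin precursor, by 1.24 ± 0.21. Tac1, the precursor of substance P in the same pathway, did not pass (-0.30 ± 0.14, adjusted p 0.163), nor did Eya1 (0.12 ± 0.13, adjusted p 0.540). The direct score minus the indirect score was -0.81 ± 0.17 (SD, n = 4) in wild-type and -0.29 ± 0.08 (SD, n = 5) in R6/2 mice, a difference of 0.52 (exact permutation p = 0.00794). Without the 3 arrays richest in choroid plexus transcripts the difference was 0.43, in a design too small to pass. Of single markers, 3 indirect and 1 direct passed with the cortex list score as a covariate, and 3 of each without those arrays. The difference between the 2 scores was not tested with that covariate. Single genes gave no uniform order there, with Drd1 at -1.14 ± 0.18 and Drd2 at -0.93 ± 0.19, but Pdyn at -0.76 ± 0.22 and Penk at -1.52 ± 0.17.

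Among the other neurons of the striatum, the cholinergic interneuron markers were lower and the GABA interneuron markers gave mixed values. Of 6 cholinergic markers 4 fell, and 4 adjusted over the list alone (median -0.66, camera adjusted p = 0.0177; adjusted p = 0.383 with an estimated correlation, and 0.0955 with the cortex list score as a covariate, where 0 members passed by limma). The choline transporter gene Slc5a7 fell by 1.01 ± 0.15 and the vesicular acetylcholine transporter gene Slc18a3 by 0.83 ± 0.12, while Chat, at 4.04 in wild-type mice among the dim genes, gave 0.04 ± 0.06. Of 11 GABA interneuron markers, the neuropeptide genes Npy (-0.43 ± 0.11) and Sst (-0.28 ± 0.07) fell, and 4 adjusted over the list alone. Their calls ended without wild-type mouse 47 (adjusted p 0.0658 and 0.0506), and that of Npy also without wild-type 66 (0.0676) or R62_109 (0.0568). The median of this list was 0.07 and its mean 0.04, whereas camera placed it on the lower side, and it did not pass (camera adjusted p = 0.67). After housekeeping centring the median was -0.03 and 4 members fell.

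Among glial markers, the astrocyte and microglia lists were lower. Of 16 astrocyte markers 9 fell and 0 rose, and adjusted over the list alone 10 fell and 1 rose (median -0.29, camera adjusted p = 0.000622; adjusted p = 0.314 with an estimated correlation). Slc4a4, a bicarbonate transporter, fell by 0.55 ± 0.09 and the glutamate transporter gene Slc1a2 by 0.48 ± 0.08. Gfap, the marker of reactive astrocytes, gave 0.42 ± 0.16 and did not pass over all genes (adjusted p 0.0941), but did so without wild-type mouse 49 (0.55, adjusted p 0.0293), and another of its probe sets rose by 0.56 (adjusted p 0.0414). Of 16 microglia markers 5 fell, and 10 adjusted over the list alone (median -0.51, camera adjusted p = 0.000117; adjusted p = 0.467 with an estimated correlation), among them P2ry13 (-0.73 ± 0.14), Cd68 (-0.57 ± 0.12) and Trem2 (-0.50 ± 0.10). Of 16 oligodendrocyte and myelin markers 4 fell, and 4 adjusted over the list alone, with Ugt8a, an enzyme of myelin lipid synthesis, at -0.72 ± 0.14 and Fa2h at -0.58 ± 0.13. As a list they did not pass (median -0.10, camera adjusted p = 0.11), but did so without R62_107 (adjusted p 0.00208). None of the 6 oligodendrocyte precursor markers (camera adjusted p = 0.434) or 15 endothelial and mural markers (camera adjusted p = 0.729) passed by limma, and 0 of either adjusted over the list alone. Given the cortex list score as a covariate, 0 astrocyte, 0 microglia and 0 oligodendrocyte markers passed by limma. Their medians were -0.26, -0.21 and 0.03, and the astrocyte and microglia lists kept their camera calls there. The microglia median was -0.31 without the 2 arrays of highest 3' difference. Only 2 astrocyte markers passed without the 3 arrays richest in choroid plexus transcripts, and wild-type mouse 49 stood above the other wild-type mice for this list (9.98 against 9.78 to 9.80). The spiny neuron score fell against all 6 cell-type scores tested. The difference was -0.74 against cholinergic and -1.31 against GABA interneurons, -1.03 against astrocytes, -1.06 against oligodendrocytes, -0.82 against microglia and -2.03 against cortex projection neurons. Each had an exact permutation p = 0.00794, which was also its adjusted value.

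**Figure D3:**
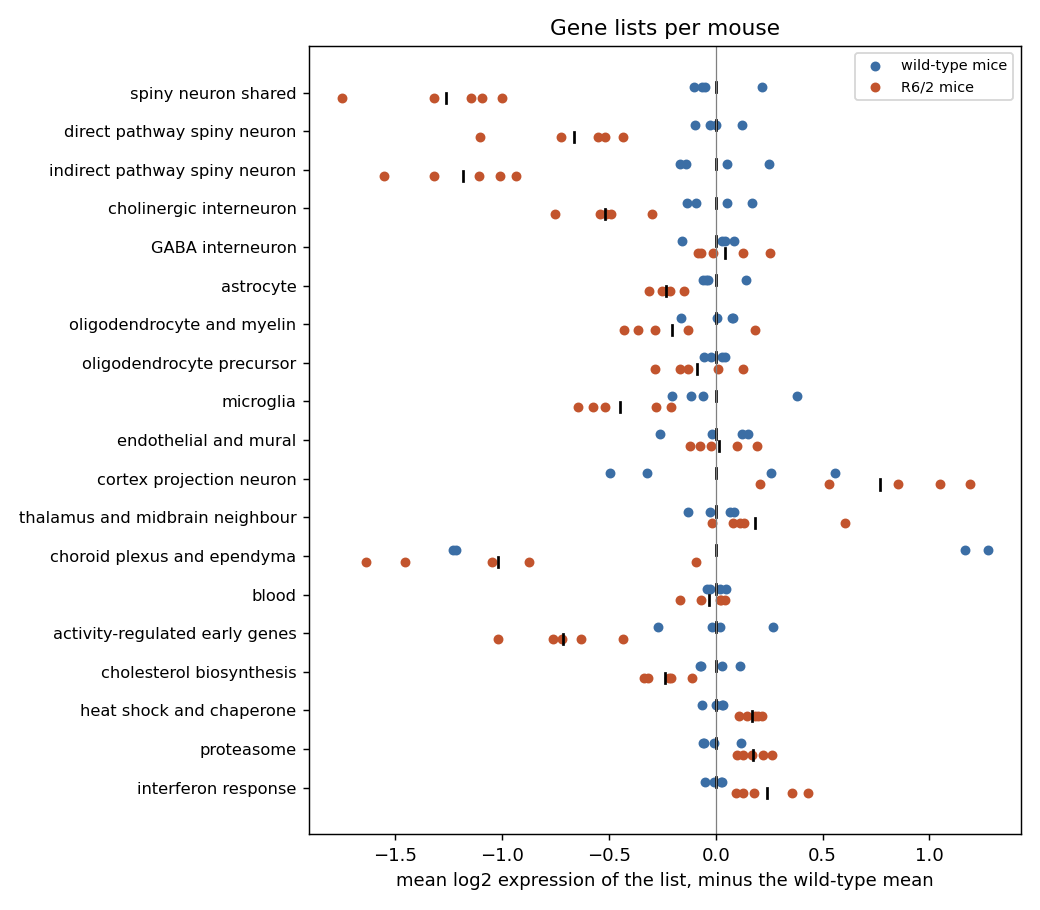
Mean log2 expression of 19 gene lists in each mouse, minus the wild-type mean (x axis). Points are mice, 4 wild-type and 5 R6/2, and black bars are group means. All R6/2 mice lie below all wild-type mice for the shared spiny neuron, direct, indirect, cholinergic, astrocyte, microglia, activity-regulated and cholesterol lists. They lie above all wild-type mice for the heat shock and interferon lists. The choroid plexus list splits the wild-type mice, with 47 and 66 at 1.17 and 1.27 and 46 and 49 at -1.21 and -1.23.

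Of the lists for neighbouring tissue, those of cortex and choroid plexus varied most within a genotype. The SD of their scores was 0.49 and 1.41 in wild-type and 0.40 and 0.60 in R6/2 mice. Of 11 cortex projection neuron markers 4 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (median 0.91, camera adjusted p = 0.022; adjusted p = 0.476 with an estimated correlation). Neurod6 rose by 2.14 ± 0.55 and Neurod1 by 1.29 ± 0.39, both chosen after their values were seen, and Neurod2 by 0.91 ± 0.19 and Fezf2 by 0.55 ± 0.10, whereas Lamp5 fell by 0.55 ± 0.11. The cortical glutamate transporter gene Slc17a7, chosen in the same way, was 6.56 ± 1.05 (SD, n = 4) in wild-type and 8.02 ± 0.65 (SD, n = 5) in R6/2 mice (adjusted p 0.0522). The list score did not pass the exact permutation test (p = 0.0556), and the call ended without wild-type mouse 49 (camera adjusted p 0.0961) or R62_105 (0.0586). Relative to the wild-type mean, the score was 0.56 in wild-type 46, 0.26 in 47, -0.32 in 49 and -0.50 in 66. The choroid plexus and ependyma list was lower (median -0.96, camera adjusted p = 0.0306; adjusted p = 0.609 with an estimated correlation), but 0 of its 9 members passed by limma, and 0 adjusted over the list alone. Its call ended without wild-type mouse 47 (adjusted p 0.177), wild-type 66 (0.18, at a median of -0.54), R62_86 (0.0621) or R62_105 (0.0586). It also ended with housekeeping centring (0.226), with fry (0.202) and with the cortex list score as a covariate (0.621). The loss without the 3 arrays richest in these transcripts (0.893) follows from their choice by this list's score. The choroid plexus list score did not pass the exact permutation test (p = 0.214). None of 9 markers of thalamus and midbrain (camera adjusted p = 0.668) or 4 blood markers (camera adjusted p = 0.719) passed over all genes, against 0 and 2 adjusted over the list alone.

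**Figure D4:**
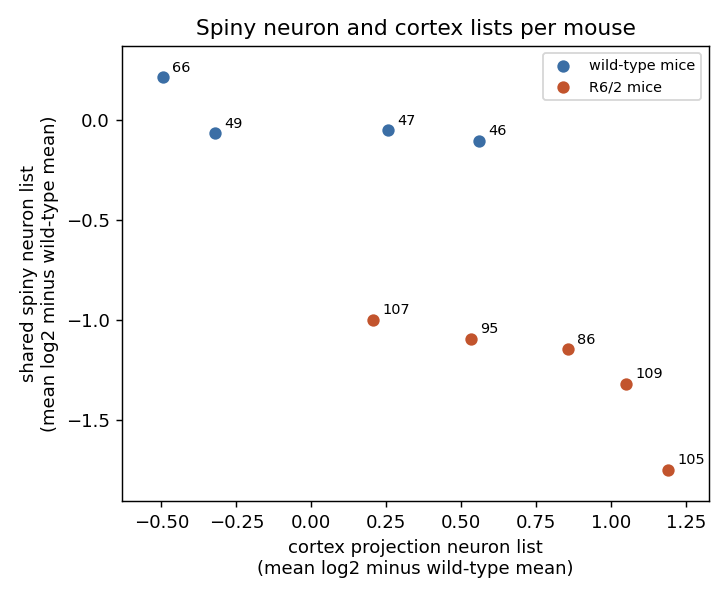
Score of the cortex projection neuron list (x axis) and of the shared spiny neuron list (y axis) in each mouse, both as mean log2 minus the wild-type mean, with the animal number beside each point. The 4 wild-type mice spread along the x axis from -0.50 to 0.56 and stay within -0.10 to 0.21 on the y axis, and the 5 R6/2 mice lie between -1.75 and -1.0 on the y axis. Among R6/2 mice the spiny neuron score falls as the cortex score rises, from R62_107 (0.21 on the x axis) to R62_105 (1.19).

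Of 22 measured genes induced by neuronal activity, 12 fell, 0 rose and 10 did not pass, and 14 fell adjusted over the list alone (median -0.72, camera adjusted p = 1.1e-06; adjusted p = 0.383 with an estimated correlation). Besides Egr2 and Npas4, Arc, which acts at synapses and was chosen after its value was seen, fell by 1.64 ± 0.30 and Homer1, a scaffold of glutamate receptors, by 0.82 ± 0.07. Nr4a2 gave 1.22 ± 0.78 (adjusted p 0.322), but -1.16 ± 0.38 with the cortex list score as a covariate (adjusted p 0.140), and passed in neither. Egr2 (-2.60 ± 0.35), Npas4 (-2.44 ± 0.38) and Homer1 (-0.73 ± 0.10) stayed lower with that covariate, and the list kept its camera call. With the cortex list score as a covariate 5 of the 22 passed, without the 3 arrays richest in choroid plexus transcripts 5, and with age as a covariate 0 by limma, at a median of -0.39.

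Signalling and channel genes were next. Of 31 calcium handling and calmodulin genes, 15 fell and 5 rose, and adjusted over the list alone 17 fell and 7 rose (median -0.23, camera adjusted p = 0.000157; adjusted p = 0.383 with an estimated correlation). The calmodulin kinase gene Camk4 fell by 1.34 ± 0.14, its activator Camkk2 by 0.91 ± 0.09 and the calcium pump gene Atp2b2 by 0.69 ± 0.07, and the channel subunit gene Cacna2d1 rose by 0.32 ± 0.07. Of 28 potassium channel genes, 12 fell and 3 rose, and adjusted over the list alone 13 fell and 3 rose (median -0.19, camera adjusted p = 0.000658; adjusted p = 0.314 with an estimated correlation). Kcnab1 fell by 1.14 ± 0.13, Kcnh3 by 0.90 ± 0.10 and the inward rectifier gene Kcnj4 by 0.82 ± 0.08, and Kcnd3 rose by 0.40 ± 0.09. With the mean of a gene's probe sets, Cacna2d1 (adjusted p 0.284), Kcnd3 (0.168) and Creb1 (0.153) did not pass. With the cortex list score as a covariate 0 calcium genes rose and 6 fell, 0 potassium channel genes rose and 7 fell, and 4 cyclic nucleotide genes rose and 0 fell. The calcium and potassium lists kept their camera calls there. Camk4 was -1.25, Camkk2 -0.96, Atp2b2 -0.66, Kcnab1 -0.89, Kcnh3 -0.71 and Kcnj4 -0.91, against 0.24 for Cacna2d1 and 0.25 for Kcnd3. Without the 3 arrays richest in choroid plexus transcripts the calcium list had 0 higher and 8 lower, and the potassium list 0 higher and 7 lower. Of 29 cyclic nucleotide genes 7 rose and 7 fell, and adjusted over the list alone 10 each way, with a median of 0.14 (camera adjusted p = 0.34). Prkar2a, a regulatory subunit of protein kinase A, rose by 0.68 ± 0.09, Pde4d, a phosphodiesterase, by 0.59 ± 0.07 and Creb1, a cyclic AMP-responsive transcription factor, by 0.50 ± 0.06, while the anchoring protein gene Akap5 fell by 0.90 ± 0.15.

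Synaptic genes followed. Of 24 glutamate receptor and scaffold genes 8 fell and 2 rose, and adjusted over the list alone 9 fell and 2 rose (median -0.10, camera adjusted p = 0.0715, but 0.00917 without wild-type mouse 49). The score of this list passed the exact permutation test (adjusted p 0.0403). Grik2 fell by 0.97 ± 0.09, Grm5 by 0.65 ± 0.10 and the scaffold gene Dlg4 by 0.63 ± 0.10, and Grin3a rose by 0.89 ± 0.20, a call that ended without moderation (adjusted p 0.0625). Of 16 genes of GABA synthesis and receptors 5 fell and 4 rose, and adjusted over the list alone 7 fell and 4 rose (median -0.17, camera adjusted p = 0.381). Here too the list score passed the exact permutation test (adjusted p 0.0437). The GABA-A receptor subunit gene Gabrd fell by 1.63 ± 0.15 and Gabra4 by 0.51 ± 0.11, while Gabra3 rose by 1.10 ± 0.22. Given the cortex list score as a covariate, Grin3a (0.49 ± 0.23) and Gabra3 (0.45 ± 0.13) did not pass, and 2 glutamate and 1 GABA gene fell and 0 rose. Without the 3 arrays richest in choroid plexus transcripts, 3 glutamate genes fell and 0 rose, and 1 GABA gene fell and 1 rose. Of 26 synaptic vesicle genes 5 rose and 1 fell, and the counts were the same adjusted over the list alone (median 0.16, camera adjusted p = 0.0338; adjusted p = 0.512 with an estimated correlation). Syp, encoding synaptophysin, rose by 0.80 ± 0.15 and Sv2a by 0.43 ± 0.08, and Cplx2, encoding complexin, fell by 0.71 ± 0.10. The call of this list ended without wild-type mouse 49 (adjusted p 0.287) or R62_86 (0.0564), R62_105 (0.0639) or R62_109 (0.0572), and with the cortex list score as a covariate (0.777). It also ended among the brighter 50% of genes (0.32), with array weights (0.112), with fry (0.142) and without the 2 arrays of highest 3' difference (0.234). The synaptic vesicle score did not pass the exact permutation test (p = 0.0873). Of its members 0 rose and 1 fell both with that covariate and without the 3 arrays richest in choroid plexus transcripts.

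Proteasome and heat shock lists were higher relative to the other genes, while the autophagy and endoplasmic reticulum stress lists did not pass by camera. Of 28 proteasome subunit genes 9 rose and 0 fell, and 12 rose adjusted over the list alone (median 0.17, camera adjusted p = 1.19e-05; adjusted p = 0.383 with an estimated correlation), with Psmd11 at 0.43 ± 0.09 and Psmd1 at 0.32 ± 0.06. Of 18 heat shock and chaperone genes 5 rose and 0 fell, and 5 rose adjusted over the list alone (median 0.17, camera adjusted p = 0.00778; adjusted p = 0.314 with an estimated correlation). Dnajb1 rose by 0.41 ± 0.07 and Hspa8 by 0.37 ± 0.06. With the mean of a gene's probe sets, Psmd11 (adjusted p 0.124) and Hspa8 (0.296) did not pass. After housekeeping centring 1 proteasome gene and 2 heat shock genes passed, and without the 3 arrays richest in choroid plexus transcripts 0 and 1 did by limma. Without the 2 arrays of highest 3' difference 16 proteasome genes rose. With the cortex list score as a covariate 0 of either passed by limma, while both lists kept their camera call. Among the brighter 50% of genes the heat shock list did not pass (camera adjusted p 0.172). Of 19 autophagy and lysosome genes 3 rose, and 3 adjusted over the list alone, among them the kinase gene Ulk1 (0.51 ± 0.11) and the cargo receptor gene Sqstm1 (0.38 ± 0.06). This list did not pass by camera (median 0.09, camera adjusted p = 0.181), but its score passed the exact permutation test (adjusted p 0.0437). After housekeeping centring the list's median was -0.02 and Ulk1 did not pass (adjusted p 0.0598). Of 16 endoplasmic reticulum stress genes 4 fell and 1 rose, and adjusted over the list alone 5 fell and 2 rose (median -0.05, camera adjusted p = 0.401), with Sdf2l1 at -0.54 ± 0.09 and Herpud1 at 0.40 ± 0.08. Of these 1 fell without the 3 arrays richest in choroid plexus transcripts, and 0 passed by limma with the cortex list score as a covariate.

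Genes of cholesterol synthesis were lower and those of respiration gave small values. Of 19 cholesterol genes 7 fell, and 8 adjusted over the list alone (median -0.18, camera adjusted p = 0.00156; adjusted p = 0.457 with an estimated correlation). Msmo1 fell by 0.86 ± 0.14, Idi1 by 0.68 ± 0.13 and Cyp51 by 0.49 ± 0.10. By limma 0 cholesterol genes passed with the cortex list score as a covariate, and 1 without the 3 arrays richest in choroid plexus transcripts, while the list kept its camera call in both. Msmo1 (-0.81 ± 0.20), Idi1 (-0.61 ± 0.18) and Cyp51 (-0.56 ± 0.14) stayed of like size with that covariate. Of 36 oxidative phosphorylation genes Cyc1 alone rose by its brightest probe set (0.20 ± 0.06, adjusted p 0.0496), 0 passed adjusted over the list alone, and the median was 0.01 (camera adjusted p = 0.434). The call of Cyc1 ended without any 1 of 8 mice, all but wild-type 49, with adjusted p between 0.0735 and 0.127. Tested as single probe sets, Cyc1 did not pass (adjusted p 0.0636), and a probe set of Sdha other than its brightest rose by 0.35 (adjusted p 0.00517). Without the 2 arrays of highest 3' difference 4 of the 36 genes rose. Of 15 circadian clock genes 5 fell, and adjusted over the list alone 6 fell and 1 rose (median -0.17, camera adjusted p = 0.0338; adjusted p = 0.459 with an estimated correlation). Npas2, a partner of the clock protein ARNTL, fell by 1.31 ± 0.08, with an adjusted p of 3.19e-05, and Hlf fell by 0.60 ± 0.08. The call of this list ended without wild-type mouse 46 (adjusted p 0.0719) or 66 (0.0988, at a median of -0.10), with housekeeping centring (0.0933), with age as a covariate (0.0659) and without the 3 arrays richest in choroid plexus transcripts (0.137). Its median was -0.26 without wild-type 49 and -0.09 without R62_105. Of its members 2 passed with the cortex list score as a covariate.

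Of 20 interferon response genes 5 rose, and 5 adjusted over the list alone (median 0.21, camera adjusted p = 0.0177; adjusted p = 0.476 with an estimated correlation, and 0.0692 without R62_107). The call also ended among the brighter 50% of genes (0.489), with fry (0.0674) and without the 2 arrays of highest 3' difference (0.0684). The median was 0.12 without wild-type 46. After housekeeping centring 3 rose and 1 fell, 1 rose without the 3 arrays richest in choroid plexus transcripts, and 0 passed by limma with the cortex list score as a covariate, where the list kept its camera call. Ifit3 rose by 0.69 ± 0.11 and Oasl2 by 0.62 ± 0.14, and with the cortex list score as a covariate they were 0.60 ± 0.16 and 0.80 ± 0.19. Oasl2 lay at 3.89 to 4.29 in wild-type mice, among the dim genes. Of 15 p53 targets and cell death genes 4 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose (median -0.01, camera adjusted p = 0.434). The growth arrest gene Gadd45g fell by 0.84 ± 0.12 and Cdkn1a by 0.49 ± 0.10, and Bcl2l11, a promoter of apoptosis, rose by 0.49 ± 0.10, but did not pass with the mean of its probe sets (adjusted p 0.154). With that covariate, and also without the 3 arrays richest in choroid plexus transcripts, 1 of the p53 targets fell. Of 15 glucocorticoid-responsive genes the metallothionein genes Mt1 (-0.57 ± 0.11) and Mt2 (-0.52 ± 0.15) fell, and 2 adjusted over the list alone (camera adjusted p = 0.558). The call of Mt2 ended without wild-type 47, R62_86, R62_95, R62_107 or R62_109, with adjusted p between 0.0531 and 0.0874. Of 29 homeobox and developmental genes 2 rose, Wt1 (0.51 ± 0.15) and Dlx1 (0.44 ± 0.13), and 0 adjusted over the list alone (camera adjusted p = 0.409). The score of this list passed the exact permutation test (adjusted p 0.0437). Wt1 lay at 3.81 to 4.02 in wild-type mice, among the dim genes. The call of Wt1 ended without any 1 of 7 mice, all but R62_105 and R62_109 (adjusted p 0.0651 to 0.0996), and that of Dlx1 without any but wild-type 47 and R62_86 (0.0698 to 0.103). None of 6 histone genes passed by limma, and 0 adjusted over the list alone (camera adjusted p = 0.552). Bdnf gave 0.16 ± 0.17 (adjusted p 0.584). The mouse gene Htt gave 0.48 ± 0.16 (adjusted p 0.0642), and since its probe sets were designed for the mouse transcript they do not check for the human transgene.

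Changed genes were not spread evenly over the chromosomes. On X, 138 of 617 genes (22.4%) changed, 96 higher and 42 lower, against 16.7% elsewhere (odds ratio 1.43, 95% interval 1.17 to 1.75, Fisher's exact test, adjusted p = 0.00782). Fewer changed on chromosome 17 (108 of 834, odds ratio 0.72, adjusted p = 0.0158) and on chromosome 7 (202 of 1413, odds ratio 0.81, adjusted p = 0.0434). These tests take genes as independent, which they are not, and the X result passed under 7 of 22 alternatives, with odds ratios from 0.93 to 2.02. It ended without wild-type 46, 47 or 66, R62_86, R62_95, R62_105 or R62_107 (adjusted p 0.0579 to 0.311). That of 17 ended without wild-type 46, 47 or 66, R62_105 or R62_107 (0.0518 to 0.311), and that of 7 without any 1 of the 9 mice (0.0555 to 0.422). Of 276 windows of 10 Mb, 0 passed after adjustment, 16 had an unadjusted p under 0.05, and the lowest adjusted p was 0.342. By position in GRCm38.p6, Gprasp2 lies on X (135839034 to 135844730), as does Phex (157162075 to 157415286). Penk lies on chromosome 4 (4133536 to 4138815), Drd1 on 13 (54051183 to 54055658), Drd2 on 9 (49340360 to 49408177), Ppp1r1b on 11 (98348406 to 98357796) and Scn4b on 9 (45138624 to 45154155).

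The first principal component held 48.2% of the variance and separated the genotypes, with R6/2 mice between 9.17 and 26.8 and wild-type mice between -27.4 and -12.4. The difference between the 3' and 5' probe sets of the control gene Actb, a sign of RNA degradation, was 0.59 ± 0.14 (SD, n = 4) in wild-type and 0.68 ± 0.32 (SD, n = 5) in R6/2 mice (exact permutation p = 0.817). That of Gapdh was -0.13 ± 0.05 and -0.06 ± 0.26 (exact permutation p = 0.929). R62_95 had the highest value of both, 1.24 and 0.40. Without it and wild-type mouse 49, 3315 genes changed. Xist lay between 9.77 and 11.4. Its lowest value was that of R62_109, which also had the highest value of the Y-linked gene Eif2s3y, 5.03 against 2.91 to 3.50 in the other mice. Without R62_109, 2207 genes changed.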

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

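The tests of cortical tissue, of the share of spiny neurons and of RNA quality were chosen after the results were seen; the counts of genes and lists over other splits of the mice were fixed before. In 378 groups of values (named genes, gene lists, control ratios and the probe sets of Xist and Y-linked genes, in each genotype), 26 held a mouse far from the rest of its group, and chance gives about 5 in 100.

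Wild-type mouse 49 stood apart most often, in 8 groups of values. It was lowest of the wild-type mice for Htt (6.97), Chat (3.98, where the other 3 were all at 4.06) and Tek (5.87). It was highest for Tcf7l2 (5.05), Mt1 (12.2388), Mt2 (11.1788), the astrocyte list (9.98) and the histone list (8.61). Wild-type 66 was highest for Slc4a4 (10.469) and for the shared spiny neuron list (11.4131). Wild-type 46 was highest for Kcnd3 (8.59), a Kdm5d probe set (3.55) and a Uty probe set (3.49). R62_107 was highest of its genotype for Ugt8a (9.77) and Olig1 (11.36). R62_105 was highest for Zbtb16 (8.58) and the glucocorticoid-responsive list (8.08) and lowest for the list of GABA synthesis and receptors (9.30). R62_86 was lowest for C1ql1 (4.23). R62_95 was lowest for Sdha (11.1713) and highest for the 3' to 5' difference of Actb (1.24) and Gapdh (0.40). R62_109 was highest for Kcnd3 (9.01), the list of thalamus and midbrain (6.66) and the Y-linked genes Eif2s3y (5.03) and, at 1 probe set, Kdm5d (3.56). The other R6/2 mice had Eif2s3y between 2.91 and 3.07. R62_109 also had the lowest Xist (9.77), so a trace of RNA from a male in this sample stays open.

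Chance is argued against for the number of changed genes. The real split of the 9 mice was set against others drawn at random, 100 in all. Only the real one gave 3066 genes, and the highest other gave 495. This share of 1 in 100 is the smallest that these splits could give. For the gene lists 3 of 100 splits gave at least as many as the real 17. The highest other, with 19 lists and 0 genes, put R62_107 in place of wild-type 49 and so kept together the 3 mice richest in choroid plexus transcripts. The 3 of 100 lay under the limit fixed beforehand. For the lists chance is still not excluded, because splits that mixed the genotypes gave 19 and 18 lists, more than the real 17. The median of the other splits was 8 lists, so the number of lists past camera's preset threshold is a weak measure of genotype.

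The first pattern is the lower shared spiny neuron list in R6/2 mice. Cortical tissue in the samples is argued against as the whole cause, because with the cortex list score as a covariate the difference of the list score went from -1.26 to -0.95 (95% interval -1.36 to -0.54). A lower share of spiny neurons alone would raise the lists of 7 other striatal cell types alike. Their shifts ran from -0.52 for cholinergic interneurons to 0.04 for GABA interneurons, wider than in other splits (exact permutation p = 0.0238). Changes within those other cells would widen the shifts as well, so this test cannot tell whether fewer spiny neurons took part. Degraded RNA is argued against by the median of -1.21 (camera adjusted p 1.67e-22) without the array of each genotype with the highest Actb difference. An effect of genotype on transcription in these neurons was not tested and stays open, as does a part from cortical tissue, from fewer neurons or from the difference in age, with which a day of dissection would be confounded.

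The second pattern is the higher cortex projection neuron list. Within genotypes its members varied together more than 99.84% of 10000 random lists matched on brightness (mean correlation 0.31). With Slc17a7 as a covariate the genotype difference of the other 10 members went from 0.70 to 0.04 (95% interval -0.29 to 0.36). Random genes are a low bar for a list of cell type markers. The estimated correlation was 0.71 for the shared spiny neuron list and 0.60 for microglia, but 0.13 for astrocytes. Differing amounts of cortical tissue would give such a correlation. So would other variation that these genes share, and the percentile cannot tell them apart. Slc17a7 is itself a member of the list. Adjusting for it would lower the difference under cortical tissue and under a genotype effect on these genes alike, so that value cannot tell them apart. The cortex list moved away from the mean of the 7 striatal cell types by 0.97 (exact permutation p = 0.0317). Those 7 lists themselves shifted by -0.52 to 0.04, and the cortex score alone did not pass (exact permutation p = 0.0556). Changes within those other cells would add to the 0.97, so this test cannot tell whether a lower share of spiny neurons took part. A change of cortical genes within R6/2 striatum was not tested and stays open, as do cortical tissue and a lower share of spiny neurons.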

How the results depend on the processing

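Tests with the cortex list score as a covariate and without sets of arrays were chosen after seeing the data. Under all settings run, no named gene or list that passed with all mice changed sign. The shared spiny neuron, direct and indirect lists kept direction and call under all settings but the estimated correlation. Of 100 named genes past the threshold, 69 kept their call under all settings but age, cortex score and choroid plexus, and 4 under all. With all mice and without each in turn, 1783 genes (58.2% of the 3066) were called. Among values that never passed, 33 list values and 19 values of named genes changed sign. The causes were not tested except where stated. No paired analysis was possible because the animal numbers of the genotypes do not match. Arrays give no counts, and dim probe sets limit what can be seen.

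Age as a covariate left 30 genes, 4 higher and 26 lower, because by construction genotype then rests on 1 R6/2 mouse of the wild-type age. The odds ratio of chromosome 17 turned to 1.47. The cortex list score as a covariate left 506 genes, 210 higher and 296 lower, of which 485 were among the 3066, and the odds ratio of X turned to 0.93. Without the 3 arrays richest in choroid plexus transcripts, with 2 wild-type mice left, 882 genes passed, 393 higher and 489 lower, and the endothelial and mural list, which had not passed with all mice, turned from a median near 0 to 0.14 and passed as higher. There the direct minus indirect difference was 0.43. The shared spiny neuron score differed by -0.71 from the cholinergic, -1.28 from the GABA interneuron, -0.94 from the astrocyte, -0.99 from the oligodendrocyte, -0.61 from the microglia and -2.03 from the cortex score, and 2 against 4 mice cannot reach the threshold.

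By construction, stricter thresholds gave fewer genes. A log2 difference of at least 1 left 198 (48 higher, 150 lower), an adjusted p under 0.01 left 1257 (607 higher, 650 lower) and a test against 0.2 left 709 (260 higher, 449 lower). Without moderation 2006 genes passed, 1081 higher. Housekeeping centring gave 696 higher and 2525 lower. Without each mouse in turn, 2183 to 2984 genes passed, 1120 to 1699 of them higher.

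With an estimated correlation, 0 lists were called higher and 0 lower, with the same medians (spiny -1.19, direct -0.46, indirect -1.58, cortex 0.91). Lists called higher were 1 with the brighter 50% of genes, 3 with array weights, 3 with fry, 3 without the 2 arrays of highest 3' difference and 3 to 5 without each mouse. The cortex list lost its call with the brighter genes (0.64), array weights (0.85), fry (0.91) and without the 2 arrays of highest 3' difference (0.87), and was 0.73 to 1.04 without each mouse. Some lists did not pass camera with all mice but passed under an alternative. The glutamate receptor list did so with brighter genes, array weights, cortex score, fry and without the 2 arrays of highest 3' difference. The oligodendrocyte list did so with brighter genes, age and without choroid plexus arrays. So did autophagy (cortex score), cyclic nucleotide (fry) and oxidative phosphorylation (without the 2 arrays). Without those 2 arrays the spiny minus cortex difference was -2.04 and did not pass. The number of chromosomes that departed, 3 with all mice, was 0 with the mean of probe sets, housekeeping centring, array weights, age, cortex score, without choroid plexus arrays and at an adjusted p under 0.01, and 0 to 2 without each mouse.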

Other observations

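The gene families by symbol and the tests of X with the cortex list score and over other splits of the mice were chosen after the results were seen. Of 90 families of at least 20 genes that share a symbol stem, 7 passed with camera's preset correlation and 0 with an estimated one. Rgs genes, regulators of G protein signalling, were lower (9 of 21 lower and 2 higher, median -0.23, camera adjusted p = 0.00555). On the higher side were Ddx helicases (9 of 35 higher and 1 lower, median 0.14), Polr polymerase subunits (5 of 25 higher and 0 lower, 0.16), Snx sorting nexins (6 of 30 higher and 1 lower, 0.14) and Eif translation factors (8 of 47 higher and 1 lower, 0.11). Camera also placed Usp proteases there (13 of 51 higher and 2 lower, 0.08) and Zfp zinc finger genes (38 of 336 higher and 10 lower, 0.06). Housekeeping centring lowers every median by the same amount, to 0.03 for Ddx, 0.05 for Polr, 0.04 for Snx, 0.0015 for Eif, -0.02 for Usp and -0.05 for Zfp, so these rises hold only relative to the other genes.

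The excess of changed genes on X was weighed as well. Brightness of the probe sets is argued against, since the odds ratio stratified by brightness was 1.57 (95% interval 1.27 to 1.93). With the cortex list score as a covariate it was 0.93 (0.52 to 1.53), from 16 changed genes on X, so cortical tissue cannot be told apart from an effect of genotype. Of 100 splits of the mice only 3 called at least 100 genes, too few for a share under 0.05. The real 1 of these gave 1.43 and the highest other 1.01. No biological explanation was tested.

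Changed genes were longer than genes of like brightness. The lower genes had a median genomic length of 25.6 kb against 23.4 kb in matched random lists (21.5 to 25.2), above 99.2% of 1000 lists. The higher genes had 30.9 kb against 25.4 kb, above 100%, so length goes with change in both directions. A tendency of longer genes to fall is consistent with the 99.2%, but the higher genes were longer still.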
